A study of Drosophila melanogaster with 4 samples.

How the data were processed

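Total RNA was measured by RNA-seq in 4 libraries of whole Drosophila melanogaster embryos, 2 of group H3.2-WT and 2 of group H3.2-K4R. Per the labels' protocols, eggs were laid over 2 h at 25 °C and aged for 16 h, so that the embryos were 16 to 18 h old. Embryos lacking both copies of the histone gene complex were picked by a GFP marker. RNA was purified on silica columns, and about 0.25 µg of total RNA went into each library, made with a Tecan kit that depletes Drosophila ribosomal RNA. The groups and replicate numbers were taken from the sample labels. The count table calls its wild-type columns HWT, and these were taken as H3.2-WT, the only wild-type group of the series, by stage and replicate number. Nothing in the labels says that the replicates came from separate collections, so the p-values of single genes measure the spread between these libraries, which may be technical. The p-values of gene lists at a preset inter-gene correlation, described below, mainly weigh the spread between genes.

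The deposited table holds whole-number counts of read pairs per gene, made by featureCounts 2.0.6 of the Subread package per the file headers. The header gives the options: pairs were counted as 1 fragment, on 1 strand, over exons summed by gene, with a gene annotation of build dm6. Per the file headers, neither the option to count multi-mapping reads nor the option to count reads over several genes was set. The submitters' processing notes name STAR 2.7.7a, SAMtools 1.9, Subread 2.0.6 and build dm6. With these settings a pair that maps equally well to several copies is not counted, which lowers or removes the counts of the histone gene repeats and of near-identical families such as Hsp70, the short peptidoglycan recognition proteins, the amylases and the serine proteases of the gut. Because strand was used, antisense neighbours are counted apart. Gene symbols are those of the table. They were matched to current symbols through the RefSeq gene table of assembly Release 6, and coordinates are those of the table, in build dm6. GC content was not analysed here.

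Depth was 33882742 and 45509930 counted pairs in H3.2-WT replicates 1 and 2, and 42661669 and 37055590 in H3.2-K4R replicates 1 and 2. Of 16727 genes in the table, 2858 had a count of 0 in all libraries, and 11562 were kept by edgeR's filterByExpr (minimum count 10, minimum total 15). All 4 columns of per-sample values were used. The main test was edgeR 4.0.16 in R 4.3.3: TMM normalisation, the quasi-likelihood test of H3.2-K4R against H3.2-WT without a block, and Benjamini-Hochberg adjustment over the tested genes, with a threshold of 0.05. Fold changes are log2 values of H3.2-K4R over H3.2-WT with their standard error (SE), and CPM values use the TMM library sizes. Confidence intervals of fold changes are at 95% and use the test's degrees of freedom. With 2 against 2 libraries, an exact two-sided permutation test of a single value cannot give a p below 0.333, so single values are given per library or with an SD and without such a test.

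Before the data were examined, 34 gene lists, the tests and the rule for naming genes were fixed, and the choices made later are named as such. The lists cover Hox and other Polycomb target genes, the regulators of the mark, histone genes, tissues of the late embryo, stage markers, stress responses and housekeeping groups. Lists with 3 or more tested members, 33 in all, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 on edgeR log2 CPM (prior count 2), adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Lists given as name patterns were matched to the table's symbols and to the current symbols. The second matching was added after results had been seen, and it raised the tested oxidative phosphorylation genes from 8 to 67 and the digestive enzymes from 37 to 42. Of the fixed symbols, tal, Cdk1 and E2f1 had no match.

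The text names genes in 3 ways. The first takes genes past the threshold with a mean log2 CPM of at least 1, with groups that do not overlap and with a name other than a number of the CG or CR series or a small RNA: the 12 largest increases and 12 largest decreases, or all where fewer pass. The second takes up to 4 members with the lowest p from each list. The third takes the 8 Hox genes, en, inv, chosen Polycomb and Trithorax group genes, histone H3 genes, and roX1 and roX2. Any other gene is said to have been chosen after its values were seen.

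The tests were tried on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed. Over 11205 simulated genes, the edgeR test recovered 38 of 67 genes changed by 1 log2 unit, 64 of 67 changed by 2 and 61 of 66 changed by 3, and it called 9 of 11005 unchanged genes. For a simulated list of 80 genes lowered by 0.5 log2 units, camera with the preset correlation called the list and none of 99 unchanged lists. With the estimated correlation the same list had an adjusted p of 0.953, and with fry 0.496. Simulated genes were drawn independently, so this does not try the preset correlation on correlated genes, and 1 shift of 1 size does not cover larger ones. In the real lists the estimated correlation reached 0.619 (digestive enzymes), with 0.440 for cytosolic ribosomal proteins.

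Alternatives were DESeq2 1.42.0, limma-voom, DESeq2-type size factors, no filter, a filter at 1 CPM in 2 libraries, the replicate number as a block, leaving out the replication-dependent histone genes or the 10 most counted genes, and leaving out each library in turn. An exon-length correction was added after seeing the data: in each library a loess trend (span 0.3) of log2 deviation from the gene's mean on log2 exon length was removed. On simulated counts with a slope of 0.2 log2 units per doubling of length in 1 library, it took the Spearman correlation of fold change with length from 0.442 to -0.00718 over 5496 genes.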

Results

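RNA levels were measured in late Drosophila embryos, 16 to 18 h old, that lacked the endogenous replication-dependent histone gene complex and lived on a transgene with 12 copies of the histone genes. In H3.2-WT the transgenic histone H3 was wild type. In H3.2-K4R it carried arginine in place of lysine 4, the residue whose methylation marks active genes and is laid down by Set1 and the Trithorax group enzymes trx and trr. The variant histone H3.3 was still made from its own genes. The comparison addresses the role that the title of the series names for this lysine, in opposing Polycomb repression and in supporting target gene expression. There were 2 libraries per group, with 33882742 and 45509930 counted read pairs in H3.2-WT and 42661669 and 37055590 in H3.2-K4R. Across genes, log2 CPM correlated with r = 0.967 between the H3.2-WT libraries and 0.952 between the H3.2-K4R libraries, and between 0.931 and 0.958 across groups. The libraries of each group differed by far more than sampling noise, with a chi-square per degree of freedom of 56.6 in H3.2-WT and 98.1 in H3.2-K4R. In 51.0% of tested genes the groups did not overlap, where chance gives 33.3% for 2 against 2 libraries. Genes share differences between libraries, so this excess is no test of a group effect. H3.2-K4R replicate 1 correlated at 0.958 with each H3.2-WT library and at 0.952 with H3.2-K4R replicate 2. On the first principal component, which held 53.6% of the variance, H3.2-K4R replicate 2 stood farthest out at 75.8, against 0.691 for H3.2-K4R replicate 1 and -45.5 and -31.0 for H3.2-WT replicates 1 and 2.

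Of 11562 genes tested, 48 were higher and 20 lower in H3.2-K4R (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 46 and 19 of them changed 2-fold or more. Dro, which encodes the antimicrobial peptide Drosocin, rose by 4.01 ± 0.62 log2 units (SE, n = 2 per group), from 13 and 10 counts to 250 and 135 (adjusted p = 0.0425; 4.05 and 0.125 with limma-voom). PGRP-SC2, an amidase that degrades peptidoglycan, rose by 3.25 ± 0.41 (adjusted p = 0.0248), from 3.44 ± 0.323 to 32.6 ± 19.4 CPM (SD, n = 2 each). The serpin Spn88Eb rose from 1.85 ± 0.620 to 15.8 ± 0.152 CPM (adjusted p = 0.014), and the larval storage protein gene Lsp1gamma from 1.44 ± 0.128 to 8.46 ± 0.506 CPM (adjusted p = 0.03). Among decreases, Try29F, a trypsin-like protease, fell by 2.14 ± 0.25 log2 units, from 81.1 ± 17.6 to 18.3 ± 5.30 CPM (adjusted p = 0.0224). Without H3.2-WT replicate 2, edgeR called 1 gene higher (CG1850) and 0 lower, with 1036 at an unadjusted p under 0.05, and without H3.2-WT replicate 1 it called 26 and 6. In each of these fits, and without H3.2-K4R replicate 1, all 68 genes kept their direction. The groups did not overlap in any of the 68, so leaving out 1 library could hardly turn a sign.

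**Figure D1:**
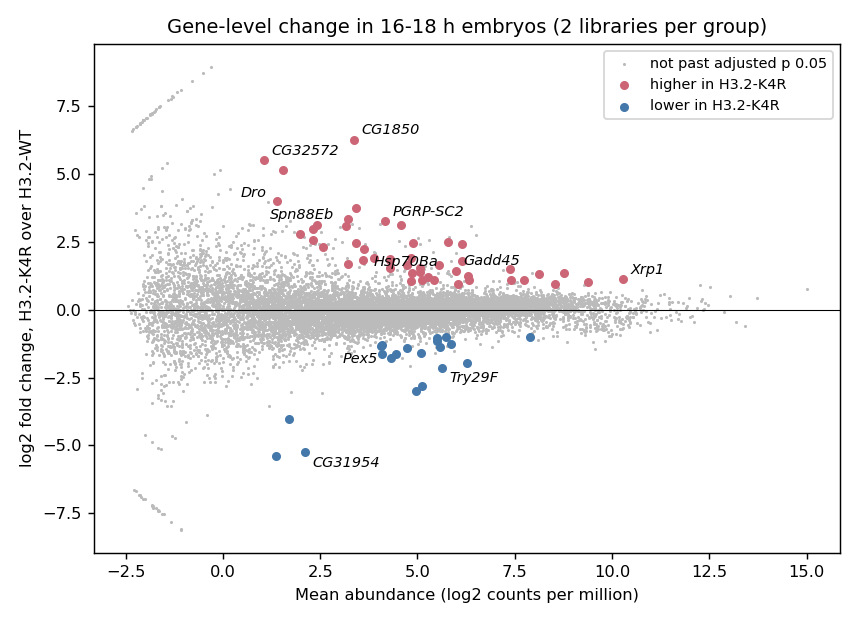
Each point is 1 of the 11562 tested genes, with mean abundance in log2 CPM on the horizontal axis and the log2 fold change of H3.2-K4R over H3.2-WT on the vertical axis. Red points mark the 48 genes that were higher and blue points the 20 that were lower at an adjusted p under 0.05, with CG1850 the highest of them at 6.26 and CG40472 the lowest at -5.40.

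The fixed rule for naming genes gave 12 increases and 4 decreases. The other increases were the cuticle protein genes Cpr64Ac (2.32 ± 0.32) and Cpr60D (1.69 ± 0.26), the heat shock genes Hsp70Ba (2.22 ± 0.30) and Hsp27 (1.80 ± 0.24), the nuclear receptor gene Hr38 (1.84 ± 0.25), the metallothionein gene MtnD (1.81 ± 0.29), the maltase gene Mal-A1 (1.65 ± 0.19) and Prat2 of purine synthesis (1.53 ± 0.18), with adjusted p between 0.0208 and 0.0459 over these 8. Hsp70Ba has near-identical copies, and pairs that mapped to several of them were not counted, so its level is uncertain. The remaining decreases were the odorant binding protein gene Obp83cd (-1.63 ± 0.25), Pex5, the receptor that brings enzymes into peroxisomes (-1.30 ± 0.20), and the copper importer gene Ctr1B (-1.17 ± 0.16), with adjusted p between 0.0334 and 0.0422. Ctr1B lay at 62.4 ± 1.49 CPM in H3.2-WT and 27.8 ± 2.75 in H3.2-K4R (SD, n = 2). With the exon-length trend removed, Ctr1B (-0.98, adjusted p = 0.058) and Obp83cd (-1.44, 0.058) kept most of their fold changes and were not past the threshold. Of the 21 named genes past it, 0 passed without H3.2-WT replicate 2, Spn88Eb and Try29F passed without H3.2-WT replicate 1, and all but Cpr60D (0.0641) and Pex5 (0.0544) without H3.2-K4R replicate 2.

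**Figure D2:**
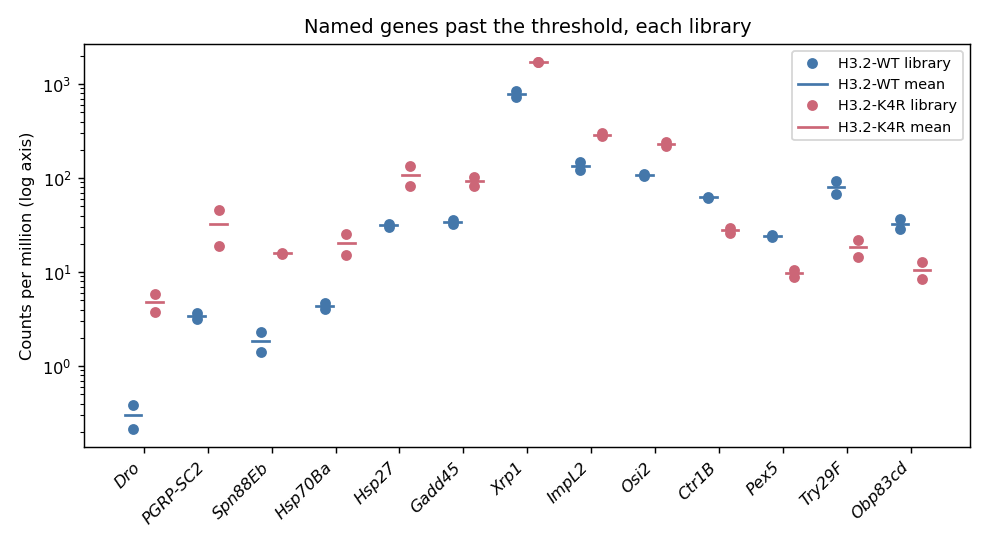
CPM on a log axis for 13 named genes past the threshold, with a point per library (2 per group) and a bar at the group mean, H3.2-WT in blue and H3.2-K4R in red. In each gene both H3.2-K4R libraries lie on the same side of both H3.2-WT libraries, for example Xrp1 at 839 and 732 against 1710 and 1705 CPM.

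Of the called genes, 42 carry a number of the CG or CR series in the count table, and 6 of the CG genes have a current name. Those that changed 16-fold or more, chosen after their values were seen, had few counts in 1 of the groups. CG1850 (chromosome 2R, 7258867 to 7261269) had 9 and 12 counts in the H3.2-WT libraries and 826 and 759 in the H3.2-K4R libraries. CG32572 (X, 16721183 to 16726948) had 1 and 6 against 192 and 123, and CG13905, now named mat (3L, 902898 to 903810) 7 and 5 against 305 and 141. In the other direction, CG31954 (2L, 3509058 to 3510102) had 316 and 347 counts in H3.2-WT and 9 and 8 in H3.2-K4R, and CG40472 (3L, 24927130 to 24927708) had 140 and 268 against 5 and 4. Dro and snoRNA:Psi28S-1175c were the other genes of this size, the latter at -4.01 ± 0.50. CG1850 was the only gene that passed in every fit with 1 library left out.

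The Hox genes, the classical targets of Polycomb repression, did not pass in either direction. Their log2 fold changes ran from -0.31 ± 0.25 (SE) for pb to 0.19 ± 0.17 for Ubx, with 7 of 8 below 0, a median of -0.12 and adjusted p of 0.458 or more (edgeR). The 95% interval was -0.20 to 0.58 for Ubx, -0.55 to 0.09 for Abd-B, -0.36 to 0.34 for abd-A and -0.56 to 0.11 for Antp. Ubx (3R, 16656623 to 16734426) lay at 94.2 ± 10.4 CPM in H3.2-WT and 107 ± 15.6 in H3.2-K4R, and Abd-B (3R, 16927210 to 16972236) at 156 ± 7.03 and 133 ± 9.30 (SD, n = 2). The list as a whole had a camera adjusted p of 0.506, and 0 members passed over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 in edgeR and 0 by DESeq2. With the exon-length trend removed, the Hox median was -0.20 and 2 of 8 were above 0. The camera adjusted p was then 0.18 (0.744 with an estimated correlation). Over all alternatives run, fold changes of these genes lay between -0.48 and 0.33. The segment polarity genes en and inv had -0.45 ± 0.24 and -0.32 ± 0.27, neither past the threshold. All these values are totals over whole embryos. A change confined to some cells, or opposite changes in different cells, could be missed.

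Among 77 other developmental regulators known as Polycomb targets, 0 rose and 0 fell by the edgeR test, both over all genes and adjusted over the list alone (2 higher and 5 lower at an unadjusted p under 0.05; 1 higher by DESeq2). Of these, 54 had negative and 23 positive fold changes, and camera placed the list lower (median -0.21, adjusted p = 0.0251; adjusted p = 0.652 with an estimated correlation). Members with the lowest p were the neuroblast factor gene wor at 1.44 ± 0.36, the homeobox genes B-H2 at -0.87 ± 0.22, Dr at -0.65 ± 0.20 and exex at -0.56 ± 0.19. The adjusted p of the list was 0.276 without H3.2-WT replicate 2 (median -0.13), 0.0769 without H3.2-K4R replicate 1 (-0.25) and 0.0512 without H3.2-K4R replicate 2 (-0.16). Removal of the exon-length trend left the median at -0.21 with an adjusted p of 0.00914 (adjusted p = 0.673 with an estimated correlation).

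Regulators of the mark had small differences. Of 27 Trithorax group and H3K4 methylation genes, 0 passed by edgeR over all genes or adjusted over the list alone (4 higher at an unadjusted p under 0.05; 1 higher by DESeq2), 21 had positive fold changes, and camera placed the list higher (median 0.22, adjusted p = 0.0304; adjusted p = 0.64 with an estimated correlation). Examples were trx at 0.55 ± 0.14 (295 ± 23.7 against 433 ± 14.8 CPM, adjusted p = 0.139), Bap170 at 0.53 ± 0.16, trr at 0.24 ± 0.17 and Set1 at 0.01 ± 0.15. These are long genes (median exon length 5119 bases), and with the exon-length trend removed the median was 0.06 and the adjusted p 0.319. The call was also absent without H3.2-WT replicate 1 (median 0.16, adjusted p = 0.127), H3.2-WT replicate 2 (0.19, 0.0892) or H3.2-K4R replicate 2 (0.17, 0.222). The 22 Polycomb group genes had a median of 0.10 (camera adjusted p = 0.233) with 0 members past the threshold over all genes or adjusted over the list alone (2 higher and 1 lower at an unadjusted p under 0.05 in edgeR; 0 by DESeq2): E(z), the H3K27 methyltransferase gene, had 0.57 ± 0.24, Scm 0.49 ± 0.15, Pc 0.19 ± 0.17, ph-p -0.15 ± 0.14 and Psc -0.40 ± 0.15.

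Genes for translation and respiration had the lowest camera p of all lists. Of 87 cytosolic ribosomal protein genes 85 had negative fold changes (median -0.62, camera adjusted p = 4.03e-15), as had 66 of 67 oxidative phosphorylation genes (median -0.55, adjusted p = 8.53e-12) and 66 of 72 mitochondrial ribosomal protein genes (median -0.44, adjusted p = 5.14e-10). The adjusted p was 0.64 for each of the 3 with an estimated correlation. In edgeR 0 members of each list passed over all genes tested, while 55, 43 and 1 fell when adjusted over the list alone. At an unadjusted p under 0.05, 63, 45 and 36 were lower, and DESeq2 called 46, 22 and 3 lower. RpL39 went from 75.8 to 36.7 CPM in the mean (-1.04 ± 0.20), RpS16 had -0.71 ± 0.15, mRpL36 -1.05 ± 0.19 and ATPsyn-b -0.96 ± 0.19. RpS5b, a paralog of RpS5a that is best known from the germ line, had -2.08 ± 0.39. Relative to the mean of the 4 libraries, the median cytosolic ribosomal protein gene lay at 0.42 and 0.26 in H3.2-WT replicates 1 and 2 and at -0.12 and -0.52 in H3.2-K4R replicates 1 and 2. These 3 calls and that of the antimicrobial peptides were the only list calls present in every fit with 1 library left out.

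**Figure D3:**
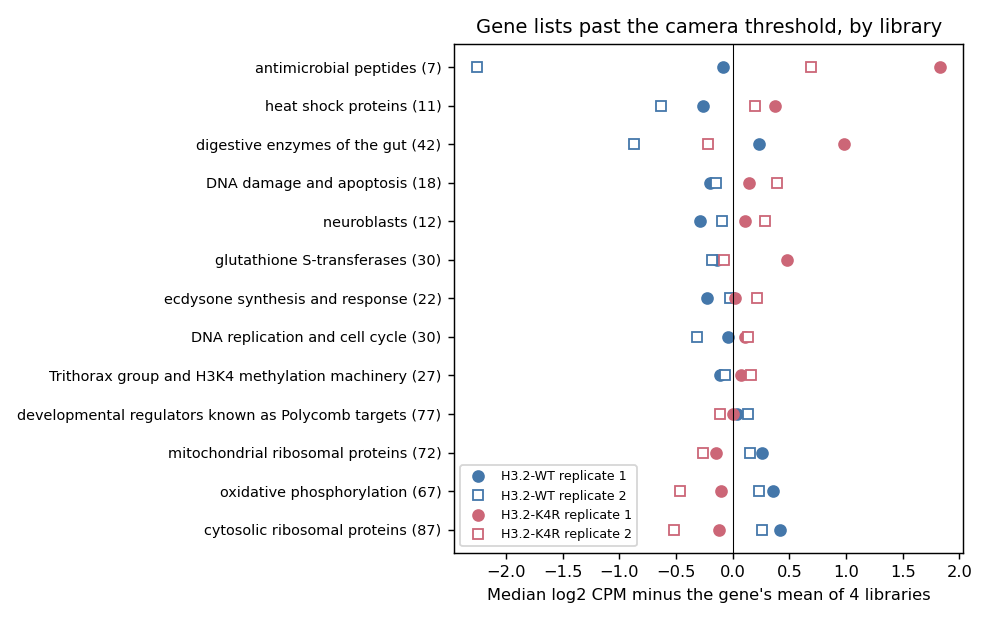
For each of the 13 lists past the camera threshold (number of tested genes in brackets), the horizontal axis gives the median over genes of log2 CPM minus the gene's mean over the 4 libraries, with a point per library. Cytosolic ribosomal protein genes lie at 0.42 and 0.26 in the H3.2-WT libraries and -0.12 and -0.52 in the H3.2-K4R libraries, while digestive enzymes of H3.2-K4R replicate 2 (-0.21) lie between the H3.2-WT libraries (0.23 and -0.87).

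Level also moved with exon length. Among 5528 genes at a log2 CPM of 4 or more, the fold change correlated across genes with exon length (Spearman rho = 0.395), and the median went from -0.34 in genes of up to 500 bases to 0.19 in genes above 6000 bases. The H3.2-WT libraries differed by length as well (rho = -0.410 for replicate 1 over replicate 2), and the H3.2-K4R libraries less (-0.203). Genes are not independent replicates, so no p is given. The ribosomal protein and respiratory lists consist of short genes (median exon lengths of 903, 844 and 783 bases), and with the trend removed their medians were -0.46 for cytosolic ribosomal proteins, -0.41 for oxidative phosphorylation and -0.27 for mitochondrial ribosomal proteins, each still past the camera threshold with the preset correlation (adjusted p = 0.659 with an estimated correlation for each).

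**Figure D4:**
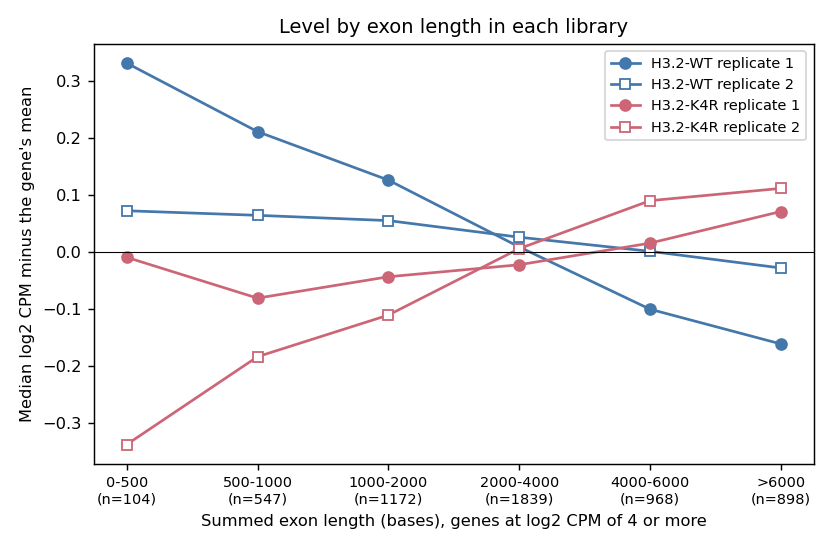
Median log2 CPM minus the gene's mean over the 4 libraries (vertical axis) by summed exon length in bases (horizontal axis), for genes at a log2 CPM of 4 or more, with a line per library and the number of genes under each bin. In the shortest bin the libraries run from 0.33 in H3.2-WT replicate 1 to -0.34 in H3.2-K4R replicate 2, and above 6000 bases from -0.16 to 0.11.

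Camera placed immune and stress lists higher. All 7 tested antimicrobial peptide genes had positive fold changes (median 2.68, camera adjusted p = 0.000126; adjusted p = 0.64 with an estimated correlation), 1 rose over all genes (Dro, not past the threshold with limma-voom, 0.125) and 4 when adjusted over the list alone. Drsl5 had 2.68 ± 0.44 and Mtk 1.56 ± 0.49. The median was 5.14 without H3.2-WT replicate 1 and 1.68 without H3.2-K4R replicate 1. The libraries of each group were far apart here, with medians of -0.09 and -2.25 in H3.2-WT and 1.83 and 0.69 in H3.2-K4R. Of 11 heat shock protein genes, Hsp70Ba and Hsp27 rose, 9 did not pass, and 5 rose and 1 fell when adjusted over the list alone (median 0.89, camera adjusted p = 0.0108; adjusted p = 0.64 with an estimated correlation). Hsp68 had 1.30 ± 0.24 and Hsp26 1.34 ± 0.27. The heat shock call was absent without H3.2-K4R replicate 1 (median 0.43, adjusted p = 0.114) or replicate 2 (0.39, 0.0518), and without a filter (0.14, 0.213), and the median was 0.54 without H3.2-WT replicate 2.

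Of 18 DNA damage and apoptosis genes, 2 rose over all genes and 5 adjusted over the list alone (median 0.40, camera adjusted p = 0.00989; adjusted p = 0.64 with an estimated correlation). Xrp1, a transcription factor gene of the damage and cell competition response, went from 786 ± 75.6 to 1707 ± 3.42 CPM (SD, n = 2; 1.12 ± 0.15, adjusted p = 0.0291), and Gadd45, a stress-activated MAP kinase regulator, from 34.5 ± 2.43 to 93.0 ± 14.7 (1.43 ± 0.18, adjusted p = 0.0248). Gadd45 (2R, 7249161 to 7250655) lies within 50000 bases of CG1850 (2R, 7258867 to 7261269), the gene with the largest increase. Whether a local difference raised both was not tested. The DNA end-joining gene Ku80 had 2.10 ± 0.53 and the death inducer skl 0.73 ± 0.18, neither past the threshold over all genes. Without H3.2-K4R replicate 2 the median of the list was 0.21 (adjusted p = 0.0991), and without replicate 1 it was 0.64. Of 30 glutathione S-transferase genes, 0 passed by edgeR over all genes (10 higher and 3 lower at an unadjusted p under 0.05; 4 and 1 by DESeq2), while 6 rose and 1 fell adjusted over the list alone (median 0.38, camera adjusted p = 0.0304; adjusted p = 0.708 with an estimated correlation). GstD3 had 2.42 ± 0.41 and GstD2 2.14 ± 0.40. Here the call rested on H3.2-K4R replicate 1, at a median of 0.48 against -0.07 in replicate 2: without it the median was 0.07 (adjusted p = 0.52), without H3.2-K4R replicate 2 it was 0.58, and without H3.2-WT replicate 1 or 2 the median was 0.36 and 0.30 (adjusted p = 0.0935 and 0.0798).

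Digestive enzyme genes had a positive median (0.54 over 42 genes, camera adjusted p = 0.0234; adjusted p = 0.708 with an estimated correlation), and Mal-A1 alone rose over all genes, with 6 rising and 2 falling adjusted over the list alone. Jon44E had 2.41 ± 0.45, Amy-p 2.11 ± 0.47 and Mal-B1 1.65 ± 0.32. Without H3.2-K4R replicate 1 the median of these genes was -0.31 (adjusted p = 0.846), and without H3.2-WT replicate 2 it was 0.20 (0.619). It was 1.56 without H3.2-WT replicate 1 and 1.25 without H3.2-K4R replicate 2.

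Neural stem cell and proliferation genes were also placed higher by camera. Over 12 neuroblast genes the median was 0.39 (adjusted p = 0.0108; adjusted p = 0.652 with an estimated correlation), with 0 past the edgeR threshold over all genes (4 higher at an unadjusted p under 0.05; 2 by DESeq2) and 3 rising adjusted over the list alone. Examples were wor, ase at 1.08 ± 0.31, nerfin-1 at 1.05 ± 0.21 and brat at 0.39 ± 0.15. Over 30 DNA replication and cell cycle genes the median was 0.25 (adjusted p = 0.0231; adjusted p = 0.64 with an estimated correlation), with 0 past the edgeR threshold over all genes or adjusted over the list alone (2 higher at an unadjusted p under 0.05; 1 by DESeq2) and CycE at 0.98 ± 0.29. Its median was 0.55 without H3.2-WT replicate 1 and 0.10 without H3.2-WT replicate 2. The neuroblast call was absent without H3.2-WT replicate 1 (median 0.30, adjusted p = 0.0935) or H3.2-K4R replicate 2 (0.32, 0.0576), and with the exon-length trend removed, where the median was 0.40 (0.073). The cell cycle call was absent without H3.2-WT replicate 2 (adjusted p = 0.491), H3.2-K4R replicate 1 (median 0.24, adjusted p = 0.0769) or replicate 2 (0.19, 0.0512). Of 22 ecdysone genes, Hr38 and ImpL2 rose and 20 did not pass, with 3 rising adjusted over the list alone (median 0.25, camera adjusted p = 0.0304; adjusted p = 0.64 with an estimated correlation). ImpL2, which encodes a secreted binder of insulin-like peptides, went from 135 ± 18.1 to 291 ± 11.8 CPM. The ecdysone call was absent without H3.2-WT replicate 1 (median 0.29, adjusted p = 0.231), H3.2-K4R replicate 1 (0.36, 0.052) or replicate 2 (0.17, 0.189), and with the length trend removed (0.19, 0.286), and the median was 0.44 without H3.2-WT replicate 2.

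The other tissue and stage lists were not called. Of 105 cuticle protein genes, Cpr64Ac, Cpr60D and Cpr47Ea rose and 102 did not pass, with 11 rising and 6 falling adjusted over the list alone (median 0.04, camera adjusted p = 0.388). With the length trend removed the cuticle list was placed higher (median 0.22, adjusted p = 0.0277; adjusted p = 0.659 with an estimated correlation). In the Osiris family, Osi2 rose from 108 ± 3.46 to 231 ± 18.5 CPM and 15 members did not pass, with 2 rising and 1 falling adjusted over the list alone (median 0.19, adjusted p = 0.174). Without H3.2-WT replicate 2 the Osiris median was 0.78. With all libraries the camera adjusted p of the Osiris list was 0.708 with an estimated correlation. Of 10 fat body genes Lsp1gamma rose, with 2 rising adjusted over the list alone (median 0.25, adjusted p = 0.229), and bmm, a lipase of fat storage, had 0.81 ± 0.15. With the length trend removed the fat body median was 0.07. Somatic muscle genes had a median of -0.23 over 19 genes (adjusted p = 0.263) and 0 members past the edgeR threshold over all genes or adjusted over the list alone (2 higher and 7 lower at an unadjusted p under 0.05; 1 and 1 by DESeq2), in which the long gene Msp300 (69801 bases of exon) had 0.83 ± 0.21 while Tm2 (2613 bases) had -0.45 ± 0.14, TpnC73F -0.43 ± 0.16 and Mlc2 -0.38 ± 0.14. With the length trend removed the muscle list was placed lower (median -0.23, adjusted p = 0.0419; adjusted p = 0.744 with an estimated correlation).

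In the nervous system lists, medians were 0.10 over 20 neuron genes (camera adjusted p = 0.191), -0.26 over 11 glia genes (0.341) and -0.41 over 21 neuropeptide genes (0.174), all with 0 members past the edgeR threshold over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 3 higher neuron genes (3 by DESeq2), 3 lower glia genes and 2 lower neuropeptide genes (0 and 0 by DESeq2). With the length trend removed the neuron list, of long genes (median exon length 6741 bases), had a median of -0.05, a downward camera direction and an adjusted p of 0.594. Examples were futsch at 0.59 ± 0.15, alrm at -0.74 ± 0.20 and Nplp1 at -0.74 ± 0.27. Medians were 0.07 for 12 trachea genes (0.562), 0.14 for 14 hemocyte genes (0.562), 0.11 for 13 early embryo genes (0.318) and 0.11 for 6 genes of dosage compensation and sex determination (0.542). Of these, Mmp1 had 0.61 ± 0.16, Hml 0.71 ± 0.23, hb 0.76 ± 0.24, roX1 0.07 ± 0.13 and roX2 -0.65 ± 0.23. In these 4 lists edgeR called 0 over all genes or adjusted over the list alone, 5 were higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called Mmp1 alone. In 4 lists the median, mean and camera direction did not share a sign: chitin and apical matrix (23 genes, median 0.06, mean -0.01, upward, 0.605; dyl at 1.07 ± 0.25), germ line (12 genes, -0.05, -0.07, upward, 0.797; vas at 1.04 ± 0.24), testis-specific genes (7 genes, -0.25, -0.08, upward, 0.506; fzo at 0.93 ± 0.36) and the Enhancer of split complex (11 genes, 0.07, -0.18, downward, 0.782; E(spl)m3-HLH at -1.70 ± 0.40). Over all genes edgeR called 0 in these 4 lists, and DESeq2 4, 2, 0 and 1. Adjusted over the list alone, 3, 1 and 0 rose in the first 3 and 1 fell in the last. Of 54 chemosensory and odorant binding protein genes only Obp83cd fell in both adjustments (median -0.14, 0.562). The 10 reference genes had a median of -0.39 (0.0728), with 0 past the edgeR threshold over all genes (5 lower at an unadjusted p under 0.05; 3 by DESeq2) and 4 falling adjusted over the list alone, among them Gapdh1 at -0.71 ± 0.20 and RpL32 at -0.55 ± 0.17. Camera on limma-voom values placed the reference genes lower (adjusted p = 0.0126). On edgeR values the adjusted p was 0.64 with an estimated correlation, and 0.114 with the length trend removed (median -0.23).

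The transgene itself could not be followed in these counts. Of 111 replication-dependent histone genes in the table, 110 had 0 counts in all libraries, including all 23 His3 copies, and pairs mapping to several copies were not counted. His2B:CG33868 had 14 and 2 counts in H3.2-WT and 10 and 12 in H3.2-K4R, which is 0.413 CPM of the library total (95% Clopper-Pearson interval 0.226 to 0.693), 0.0439 (0.00532 to 0.159), 0.234 (0.112 to 0.431) and 0.324 (0.167 to 0.566). A count of 0 allows up to 3 counts, or 0.0659 to 0.0885 CPM depending on the library. Intervals and limits cover counting error only. A change of 1 codon would not be seen in a gene-level count in any case. The H3.3 genes were measured: His3.3A lay at 130 ± 2.10 CPM in H3.2-WT and 69.2 ± 17.1 in H3.2-K4R (-0.91 ± 0.19, adjusted p = 0.098), and His3.3B at 832 ± 58.3 and 850 ± 199 (0.03 ± 0.18). The 6 histone variant genes outside the locus had a median of -0.12 (camera adjusted p = 0.297), with 0 past the edgeR threshold over all genes (1 lower at an unadjusted p under 0.05; 1 by DESeq2) and 1, His3.3A, falling adjusted over the list alone. That list had a median of -0.30 without H3.2-K4R replicate 2. With all libraries its median was -0.00804 with the exon-length trend removed, and its camera adjusted p was 0.652 with an estimated correlation.

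Chromosome arms differed little. Median log2 fold changes were -0.04 on 2L, -0.03 on 2R, -0.01 on 3L, -0.00326 on 3R, 0.02 on 4 and -0.03 on X, and called genes lay on each of these arms but 4.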

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

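The exon-length correction and the added gene groups with 1 library left out were chosen after seeing the data, as was the reported matching of list patterns to current symbols, for which the original matching to the table's symbols is the alternative; the other alternatives were chosen before. Against 48 genes higher and 20 lower, DESeq2 gave 310 and 282, limma-voom 101 and 72, no filter 452 and 527, and the replicate number as a block 608 and 758; the cause was not tested. Leaving out 1 library gave 1 to 251 higher and 0 to 587 lower, with a lone library assumed to vary like the others. Size factors of the DESeq2 type (54 and 20), the CPM filter (63 and 22), the length correction (72 and 16) and leaving out histone genes or the 10 most counted genes (48 and 20 each) stayed within 1.5 times. All 68 genes kept their direction in each of these fits. Their groups did not overlap, so leaving out 1 library could hardly turn a sign. Of the values past the threshold 1 reversed, the median of digestive enzymes (0.54), at -0.309 without H3.2-K4R replicate 1. It ranged up to 1.56 with 1 library left out, and the cause was not tested. Another 54 changes of direction concerned values past the threshold in neither fit. Higher genes were 70.6% of the calls, against 52.4% with DESeq2, 44.5% with the block, 46.2% without a filter, 58.4% with limma-voom and 81.8% with the length correction. The replicate numbers were not treated as pairs: same-numbered libraries' deviations correlated at 0.106 over 2 pairs, and the labels name no shared batch. Fry's mixed test, which takes changes of members in either direction, passed somatic muscle (adjusted p = 0.0127) and cuticle genes (0.0139). It also passed fat body (0.0139) and DNA damage and apoptosis genes (0.0145), and it gives a list no direction. Of 9 lists higher and 4 lower, 0 and 0 passed with an estimated correlation or with the directional fry test (smallest adjusted p 0.167). Leaving out 1 library gave 3 to 6 lists higher and 3 to 4 lower. The block ended the Trithorax list's call alone (adjusted p = 0.0685, in a range of 0.012 to 0.64 over its alternatives), and limma-voom, the CPM filter, the left-out genes and the table's symbols ended none. Limma-voom also left Dro short of the threshold (0.125). Arm medians moved by more than the spread of the libraries in some fits. For 2L, 2R, 3L and 3R they were -0.0039, 0.00198, 0.0257 and 0.0315 with DESeq2, and -0.0104, -0.0031, 0.0204 and 0.0249 with its size factors. With the length correction they were 0.0041, 0.0038, 0.027 and 0.0272, and 3L had 0.0054 without a filter. The median over all tested genes rose as well, from -0.0201 to 0.0109 with DESeq2 and 0.0086 with its size factors. It was 0.0095 with the length correction and -0.0093 without a filter. The arm moves thus went with a shift over all genes, and beyond that the cause was not tested. Leaving out 1 library gave -0.0745 to 0.0085 on 2L, -0.0639 to -0.0065 on 2R, -0.0384 to 0.0228 on 3L, -0.0223 to 0.0155 on 3R, -0.054 to 0.123 on 4 and -0.0781 to -0.0081 on X. The difference in histone share, 0.0506 CPM, ranged from -0.134 to 0.235 with 1 library left out. The lowest adjusted p of a Hox gene in any fit was 0.236. DESeq2 gave no adjusted p for 6 named genes. It gave a p to all 13869 genes with a count, so its own filter on mean count left these without an adjusted p.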

Other observations

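The added gene groups and the tests of the 3 patterns in this part were chosen after the results had been seen, so that the groups are not independent evidence of their direction. Camera placed fatty acid breakdown genes lower: all 14 tested genes of beta-oxidation had negative fold changes (median -0.63, camera adjusted p = 1.2e-05 over the 7 added lists; adjusted p = 0.312 with an estimated correlation). CG7461, now named Acadvl, fell from 81.7 ± 5.94 to 34.4 ± 6.29 CPM (-1.25 ± 0.18, edgeR adjusted p = 0.0394), and 6 fell when adjusted over the list alone, among them Mtpalpha at -0.74 ± 0.16. Of 13 peroxin genes, 10 had negative values (median -0.29, adjusted p = 0.0173; 0.070 at a median of -0.20 with the length trend removed, and 0.0582 at -0.39 without H3.2-K4R replicate 1; adjusted p = 0.312 with an estimated correlation): Pex5 fell, and Pex19 had -0.90 ± 0.17. On the other side CG3523, the fatty acid synthase gene FASN1, rose by 0.96 ± 0.15 (adjusted p = 0.0461; 0.107 at 0.76 with the length trend removed, an exon length of 8744 bases). All 11 genes of the insulin pathway and starvation response had positive fold changes (median 0.67, adjusted p = 2.59e-05; adjusted p = 0.169 with an estimated correlation), with ImpL2 alone past the threshold over all genes and 5 adjusted over the list alone, InR at 0.71 ± 0.14 and Thor at 0.84 ± 0.22.

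Camera placed damage signals and Toll-induced peptides higher as well. Of 12 wound and JNK response genes 10 had positive fold changes (median 0.58, camera adjusted p = 5.52e-05; adjusted p = 0.169 with an estimated correlation), 0 passed over all genes in edgeR (8 higher at an unadjusted p under 0.05) and 8 adjusted over the list alone: the cytokine gene upd3 had 2.27 ± 0.43, Ilp8 2.01 ± 0.38 and puc 0.53 ± 0.14. Of 13 Toll-induced secreted peptide genes 12 had positive fold changes (median 2.05, adjusted p = 1.2e-05; adjusted p = 0.312 with an estimated correlation), with CG18067 (Bbd) alone past the threshold over all genes, at 3.12 ± 0.43, and 6 adjusted over the list alone. The libraries of each group were far apart in these peptides, with medians of -0.31 and -1.36 in H3.2-WT and 1.57 and 0.38 in H3.2-K4R. In 9 of the 13 genes the groups did not overlap, and the median was 1.13 without H3.2-K4R replicate 1 (adjusted p = 0.0111). Of the 5 added lists that were called, all but peroxins kept their calls with any 1 library left out. Of 6 metallothionein genes MtnD alone passed over all genes (1.81 ± 0.29), while MtnA at -1.19 ± 0.25 (adjusted p = 0.0951) and MtnB at 3.26 ± 0.54 (0.0525) did not, and the list was not called (median 1.58, adjusted p = 0.0931; 0.93 without H3.2-WT replicate 2, 0.88 without H3.2-K4R replicate 1, and called without H3.2-WT replicate 1, adjusted p = 0.00576; adjusted p = 0.472 with an estimated correlation), while the 3 copper transport genes had a median of -0.35 (0.182). Of the 68 called genes, 14 had another called gene within 50000 bases, against a median of 6 in 1000 random draws, 20 of which had as many or more.

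The 226 genes for ribosomal proteins and oxidative phosphorylation had a median log2 fold change of -0.55. A length bias between libraries, as from RNA integrity or fragment selection, would give the same to other short genes. In 10000 random lists matched on exon length and expression the median was -0.15 (range -0.29 to 0.03), and 0 were as low. By that median, genes of like exon length and expression shared part of the difference. The matching used both, so it does not separate length from expression level. Matched genes were drawn independently, whereas genes of these lists move together (estimated correlation 0.440 for cytosolic ribosomal proteins, 0.286 for oxidative phosphorylation and 0.094 for mitochondrial ribosomal proteins). The range may therefore be too narrow for such lists. H3.2-K4R replicate 1 also lay below the lower H3.2-WT library (difference -0.339, against 0.125 between the H3.2-WT libraries). The H3.2-K4R libraries were farther apart, at -0.12 and -0.43. This argues against H3.2-K4R replicate 2 as the only carrier, as far as the H3.2-WT spread is a measure. Other differences between the collections and the histone genotype stay open, and a lower translational and respiratory program in H3.2-K4R embryos may be a hypothesis for new replicates.

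Camera placed immune, digestive and stress genes higher with the preset correlation (adjusted p = 0.64 with an estimated correlation for antimicrobial peptides, heat shock and DNA damage genes, 0.708 for digestive enzymes and glutathione S-transferases). Older embryos in H3.2-K4R could bring gut and larval genes. Neuroblast and cell cycle genes, which fade late in embryogenesis, had a median of 0.29 over 42 genes, with both H3.2-K4R libraries above both H3.2-WT libraries. Older embryos as the whole account would not give this. Both lists had already been called higher, however, so the outcome was known when the test was chosen. Whether the H3.2-K4R embryos were younger was not tested. For digestive enzymes, H3.2-K4R was higher within each replicate number, at 0.99 against 0.23 for replicate 1 and -0.21 against -0.87 for replicate 2. With the replicate number as a block, the camera adjusted p was 2.18e-05 at the preset correlation. The labels name no batch shared by same-numbered libraries. H3.2-K4R replicate 2 lay below the higher H3.2-WT library (-0.443), which cannot tell 1 library carrying the increase from a level shared by same-numbered libraries. For antimicrobial peptides it lay above by 0.775, and the list was still called without H3.2-K4R replicate 1 (median 1.68, adjusted p = 0.0135 with the preset correlation), which speaks against replicate 1 as the only carrier. Camera weighs the spread between genes, however, and the H3.2-WT libraries lay 2.17 apart, so that a single-library account cannot be told apart from a group difference at 2 libraries per group. For DNA damage and apoptosis genes the lower H3.2-K4R library lay above the higher H3.2-WT library by 0.293, against 0.0492 between the H3.2-WT libraries. The H3.2-K4R libraries were farther apart, at 0.14 and 0.39, and the median was 0.21 without H3.2-K4R replicate 2. This argues against 1 library alone only as far as the H3.2-WT spread is a measure. It leaves the histone genotype and the handling of the collections open.

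The 7 genes that differed 16-fold or more lay on 4 chromosome arms (2L, 2R, 3L and X), which argues against a single linked segment carried by 1 stock. Several separate segments were not tested. Within 50000 bases, CG1850 has the called gene Gadd45 (1.43) and CG32572 has CG4653, which fell (-1.33). The others of the 7 have no called gene within that distance. Replicates of a group differed by at most 1.91-fold at these genes with counts under 3 set to 3 (CG32572 had 1 and 6 counts in H3.2-WT), but close replicates follow from the choice of called genes with large differences, so this decides nothing. Variants fixed differently in the stocks and the histone genotype cannot be told apart, because each group is 1 genotype.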
